A study of Mus musculus with 20 samples.

How the data were processed

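The values analysed are the deposited table of processed values for all 20 arrays, which holds log2 values after robust multi-array averaging (RMA) per the submitters' processing notes. Those notes name Affymetrix Expression Console 1.1. Raw image files were not used here, and the genome build is not given in the sources used here. The values run from 2.11 to 13.62, array medians lie between 5.30 and 5.44, and no pair of arrays is identical (0 pairs). The table has 24558 lines, of which 7 at its foot are summaries and were left out, leaving 24551 features with 21264 gene symbols. Some 1786 symbols have several features, which cover 5072 features, and 1 feature has no symbol. Of all features, 23804 were matched to a table of mouse genes, 21840 by accession, 1412 by symbol and 552 by synonym. The match gave current names and gene spans only, and old symbols are kept with the current name in brackets.

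Per the labels, the neurons were cultured from cortices of embryonic day 17 for 8 days, and the 5 replicates of each group are separate cultures without technical repeats. Per the labels' protocols, RNA was amplified and biotin-labelled with NuGEN kits before hybridisation. The array is called by 1 name in the labels, while the feature identifiers have the form of another array of the same maker; values are used by feature, so comparisons between arrays do not depend on it. CLIP and Input arrays of the same number and genotype come from 1 culture: the design text speaks of 10 cultures, and the authors' ratio columns subtract the Input of the same number from the CLIP (largest difference 0). Residual correlations across features for same-numbered CLIP and Input arrays were 0.244, 0.261, 0.259, 0.0908 and 0.0600 in wild type and 0.221, −0.128, 0.224, 0.455 and 0.0688 in knockout. Across all features, arrays of wild-type CLIP correlated with a median r of 0.987 and of wild-type Input with 0.979, and wild-type CLIP with Input at 0.951; features are not independent replicates.

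Other columns of the authors' deposited table were checked by recomputation. Its ratio columns are log2, its fold columns are ratios of mean linear values, and the authors computed 1 deposited p-value column on the log2 ratios, comparing genotypes feature by feature. Its permutation p-values also appear in a form called adjusted, which for 99.5% of features is the median over the features of a symbol and so no correction for multiple testing. A deposited mark for features above 4 in at least 2 arrays holds for 21226 features, with 0 mismatches on recomputation. No detection calls are used here, and near the bottom of the scale log2 differences are compressed.

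Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a common prior, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all 24551 features). Genotypes were compared within CLIP and within Input on 10 arrays each, with the sign wild type minus knockout in CLIP and knockout minus wild type in Input. CLIP minus Input in each genotype and the interaction were contrasts of a fit to all 20 arrays with 1 mean per group. Group levels of Fmr1 and the diacylglycerol kinases were also compared by exact permutation tests over 252 splits of 5 against 5, two-sided, with 0.00794 as the smallest possible p. With 5 cultures per group the precision of every estimate is set by few samples. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the figures.

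Gene groups were 24 lists from general knowledge, fixed with the comparisons, tests, alternatives and naming rule before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01 on 1 value per gene, the mean of its features, with adjustment over the 24 lists of a comparison. Where the text gives an estimated correlation, camera estimated it from the residuals of each list. List medians are given relative to the median of all genes. Listed genes without a feature include Hist1h1e, Hspa1b and Ahsp. Counts adjusted over the list alone use Benjamini-Hochberg on the members of that list.

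By the naming rule, Fmr1 and all diacylglycerol kinases are always named. In each comparison so are the 8 features of largest difference in each direction that pass limma with non-overlapping groups, or the 4 of lowest p where fewer than 4 qualify, and up to 4 members of lowest p of each list described. Akap6, Spnb1, Mast2, Lrrc8d, Sash1, Tln2 and Ogdh, and Ppfia3 in the CLIP comparison, fall outside the rule and were chosen after their values were seen. A few genes and 1 functional term that the rule or the tests would name are not reported here.

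Artificial data checked the fits, with 50 features changed per size. Each feature had its spread in the real arrays, drawn independently of the other features. Changes of 0.5, 1 and 2 log2 were recovered for 54%, 90% and 100% in the genotype comparison of CLIP, 14%, 74% and 98% in Input, and 30%, 88% and 100% for CLIP against Input in wild type. In knockout 32%, 88% and 100% were recovered, and in the interaction 10%, 58% and 96%. False calls numbered 5, 6, 6, 12 and 9 in the same order. The shifted list was recovered each time, with 0 other lists called. As the artificial data hold no correlation between genes, they cannot show how the list tests behave where genes vary together.

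Alternatives were quantile normalization, centring arrays on their medians, quantile normalization within fractions, filters on the lowest tercile or lower 50% of features by mean, 1 value per symbol, a trended robust prior and array weights. Other alternatives were a different set of arrays in the fit, a replicate block, leaving out each array in turn, an absolute log2 difference of at least 0.5 and adjusted p under 0.1. A filter on the deposited mark was added after seeing the data. A gene that stayed uncalled under an alternative counts as unchanged even if its sign flipped.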

Results

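Primary cortical neurons of mouse embryos were grown for 8 days, irradiated with ultraviolet light at 254 nm to link proteins to the RNAs they touch, and profiled on 20 microarrays. The neurons were wild type or lacked Fmr1, the gene of the fragile X mental retardation protein FMRP, an RNA-binding protein that holds back the translation of many neuronal mRNAs. Each of the 10 cultures gave an Input array of total RNA and a CLIP array of the RNA recovered with an antibody to FMRP, so that 5 arrays stood in each of 4 groups. Since knockout neurons cannot make FMRP, an RNA recovered from them marks the background of the immunoprecipitation. An RNA held by FMRP should therefore be richer in wild-type than in knockout CLIP without differing in Input. The deposited log2 values cover 24551 features (probe groups of the array, most of them 1 per gene), and array medians lay between 5.30 and 5.44. Since RNA was amplified and arrays have similar medians, CLIP values show the makeup of each precipitate, not the amount of RNA recovered. The first principal component held 55.5% of the variance and parted CLIP from Input arrays.

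Fmr1 mRNA itself shows what the knockout does to both fractions. In Input it stood at 5.69 (SD 0.21) in wild type and 4.14 (SD 0.16) in knockout (exact permutation p = 0.00794, 5 against 5 cultures, two-sided). In CLIP the levels were 6.49 (SD 0.23) and 3.92 (SD 0.08), with the same exact permutation p = 0.00794, the smallest that 252 splits allow. Dgkk, which encodes the kappa member of the diacylglycerol kinases, the enzymes that turn the membrane messenger diacylglycerol into phosphatidic acid, behaved differently. Its Input level was 4.34 (SD 0.19) in wild type and 4.40 (SD 0.18) in knockout (exact permutation p = 0.611). Its CLIP level was 7.09 (SD 0.49) against 4.68 (SD 0.18), again at exact permutation p = 0.00794. Knockout levels of Fmr1 lie near the bottom of the scale, and those of Dgkk in both Inputs and in knockout CLIP lie little above them. Folds against these levels are therefore lower bounds, and the Input arrays could not show a difference in Dgkk below background.

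**Figure D1:**
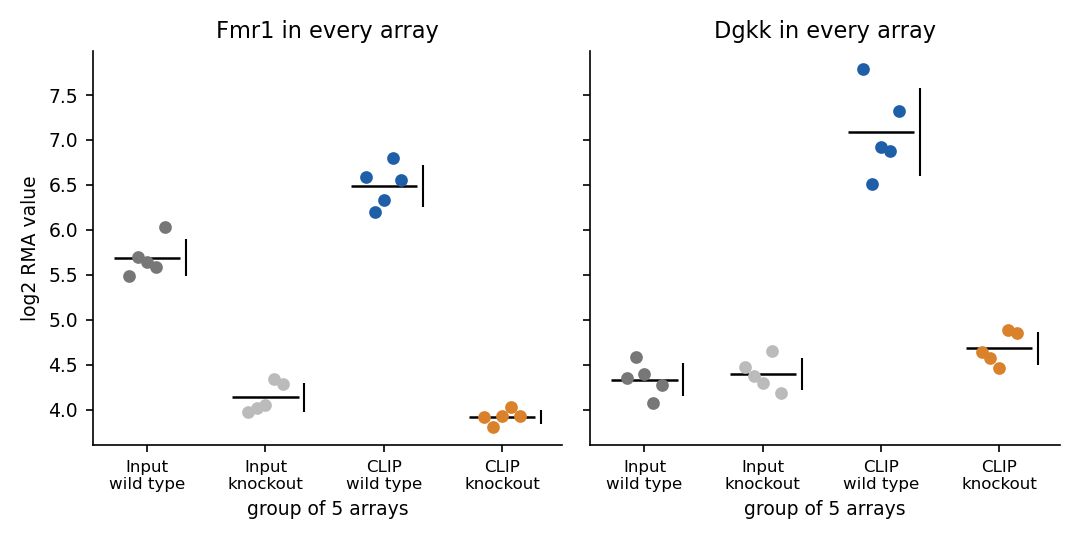
Log2 level of Fmr1 and Dgkk in every array, by genotype and fraction. Lines are group means and vertical bars 1 standard deviation of 5 arrays.

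In CLIP, the largest differences between genotypes were those of Fmr1, whose mRNA the knockout cells lack, and Dgkk. With limma, 27 features passed adjusted p under 0.05, 25 higher and 2 lower in wild type (24 and 2 gene symbols). Fmr1 was higher by 2.57 log2 (SE 0.11, adjusted p = 4.82e-07 in limma), at least 5.94-fold, a difference that also holds the loss of the mRNA from the knockout cells. Dgkk was higher by 2.40 (SE 0.20, at least 5.29-fold, limma adjusted p = 5.47e-04). The predicted gene 2610507B11Rik (1.07, SE 0.12, limma adjusted p = 0.00692) and Unc13c (1.39, SE 0.17, limma adjusted p = 0.0105) followed; Unc13c encodes a priming factor of synaptic vesicles, and its levels outside wild-type CLIP (3.92 to 4.12) are as low as those of Fmr1 in knockout, so its difference is a lower bound. Among the others were Ppfia3, an organiser of the presynaptic active zone (0.75), the beta-spectrin Spnb1 (now Sptb, 0.66), the anchoring protein gene Akap6 (0.76) and the cadherin gene Fat3 (0.81). The tumour suppressor Apc (0.92), the kinase gene Mast2 (0.70) and Gm608 (now Usf3, 0.99) passed too. Atg13, an initiator of autophagy (−0.49), and Tmem167b (−0.47) were the 2 genes lower in wild-type CLIP. Unc13c is covered by 7 features, of which 1 passed, and their differences ran from 0.13 to 1.39. For Fat3, 1 of 15 features passed, and for 4932438A13Rik 1 of 19 (from 0.27 to 1.295 over the features of Fat3 and from 0.10 to 0.82 over those of 4932438A13Rik, all above 0).

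How many RNAs pass in CLIP depends strongly on single arrays. The count of 27 was 61 without wild-type CLIP 2, and 8, 6, 5 and 4 without wild-type CLIP 1, 3, 4 and 5. It was 12, 7, 7 and 6 without knockout CLIP 1, 2, 3 and 5. Fmr1, Dgkk, 2610507B11Rik and Spnb1 passed whichever array was left out, and Akap6 was missed only without wild-type CLIP 5 (limma adjusted p = 0.0581). Unc13c was missed without wild-type CLIP 4 (limma adjusted p = 0.0584) or 5 (0.0615). Fat3 was missed without wild-type CLIP 3 (limma adjusted p = 0.0697), 4 (0.0789) or 5 (0.0905) and without knockout CLIP 2 (0.0627), 3 (0.0643) or 5 (0.0678). Gm608 was missed in 8 of 10 refits, all but those without wild-type CLIP 2 or knockout CLIP 4 (highest 0.151). Apc (highest limma adjusted p 0.18), Ppfia3 (0.13), Mast2 (0.148) and 4932438A13Rik (0.148) were missed in 9, all but the one without wild-type CLIP 2. Atg13 (limma adjusted p 0.0605 to 0.156) and Tmem167b (0.0522 to 0.139) were missed in every refit. After quantile normalization 14 features passed, all higher in wild type.

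As deposited, more RNAs were richer than poorer in wild-type CLIP, also beyond the called genes. At unadjusted p under 0.05, 1165 features were higher and 591 lower, against 1228 expected by chance in both directions together. The excess depends on scaling and on single arrays: 1051 were higher and 793 lower after quantile normalization, 975 and 664 after median centring. Without knockout CLIP 4 the ratio of higher to lower turned to 0.947 and 0.80 under these scalings. All 5 wild-type values lay above all 5 knockout values for 332 features and below them for 75, where 0.794% of features, about 195, would part completely by chance. The 25 features called higher differed by a median of 0.75 in CLIP and 0.01 in Input. Of these, 20 were higher in knockout CLIP than in knockout Input, by a median of 0.92 over all 25, where 16.2% of all features are higher. Most of the features called higher thus take a larger share of knockout CLIP than of knockout Input, whatever the amount recovered. Lrrc8d and Sash1 are not among those features, nor are Dgkk, Fmr1 and Unc13c, whose knockout levels near the floor could hide such an enrichment.

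**Figure D2:**
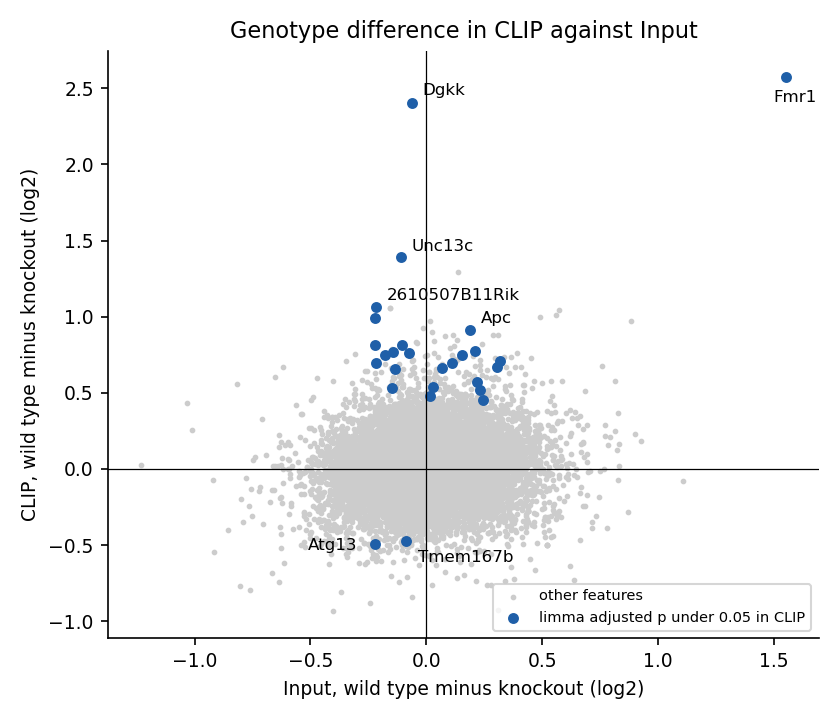
Wild type minus knockout in CLIP against the same difference in Input, for every feature. Blue marks features past limma adjusted p 0.05 in CLIP.

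Of the diacylglycerol kinases, only Dgkk passed in CLIP (1 of 10 measured genes, also when adjusted over the list alone; list adjusted p = 0.704 in limma's camera). A feature of Dgkz was higher in wild-type CLIP by 0.50 (exact permutation p = 0.00794, limma adjusted p = 0.232), while the other 2 Dgkz features lay at −0.02 each. Dgkd differed by 0.28 (exact permutation p = 0.00794, limma adjusted p = 0.551) and Dgka by −0.34 (exact permutation p = 0.0476, limma adjusted p = 0.558). Dgkh (0.17), Dgkb (−0.05), Dgke (−0.09), Dgkg (−0.04), Dgki (−0.20) and Dgkq (−0.33) did not pass either. The wider list of diacylglycerol and phosphoinositide signalling (67 genes) was higher in wild-type CLIP as a set, with a median 0.09 above that of all genes (camera in limma, adjusted p = 3.37e-04; adjusted p = 0.34 with an estimated correlation). None of its genes passed over all genes, and 6 were higher when adjusted over the list alone, among them Plcl2 (0.49), Plce1 (0.49) and Prkd3 (0.41).

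The mRNAs known from earlier work as FMRP ligands lay higher in wild-type CLIP as a group. Of 96 classic targets, Fmr1 and Apc passed over all genes, 22 were higher and 0 lower when adjusted over the list alone, and 66 had a positive difference. Their median was 0.10 above that of all genes (camera in limma, adjusted p = 4.76e-07, and adjusted p = 0.36 with an estimated correlation). These values include Fmr1, whose difference the knockout itself sets, so that its call is no sign of binding. Not taken relative to all genes, the median was 0.123 with Fmr1 and 0.120 for the other 95 targets. Examples are Huwe1 (0.53, limma adjusted p = 0.0856) and Shank3 (0.57, limma adjusted p = 0.0856), a scaffold of the excitatory synapse. The postsynaptic scaffold list (41 genes; median 0.14 above all genes; 5 higher adjusted over the list alone, with Shank3 and Dlgap3, 0.51) reached adjusted p = 1.2e-06 in limma's camera, and adjusted p = 0.34 with an estimated correlation. Voltage-gated channels (51 genes; median 0.04 above all genes; 6 higher adjusted over the list alone, with Cacna1i, 0.62, and Kcnh3, 0.54) reached adjusted p = 0.0183 in camera, and adjusted p = 0.631 with an estimated correlation. The channel list was missed without wild-type CLIP 1 (camera adjusted p in limma = 0.327) or 5 (0.113) or knockout CLIP 4 (0.504), and its median turned to −0.0006 without the first and −0.013 without the last of these. Classic targets, postsynaptic scaffold and lipid signalling passed in all 10 refits, but their sizes moved. The median of classic targets ran from 0.049 without knockout CLIP 4 to 0.146 without knockout CLIP 1, that of postsynaptic scaffold from 0.093 to 0.178 and that of lipid signalling from 0.046 to 0.126.

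Other gene groups were poorer in wild-type than in knockout CLIP. Stress response genes (33 genes, 6 of them above 0; median −0.10 against all genes) gave adjusted p = 3.35e-04 in limma's camera, and adjusted p = 0.34 with an estimated correlation, with the chaperone genes Calr (−0.42) and Hsp90b1 (−0.36) not past limma singly. GABA receptor genes (18 genes; median −0.12 against all genes; Gabrb1, −0.38, not past) gave camera adjusted p = 0.00679 in limma, and adjusted p = 0.423 with an estimated correlation. Markers of astrocytes moved with them (20 genes; median −0.08 against all genes; Slc1a2, −0.26; camera adjusted p = 0.0297 in limma, and adjusted p = 0.631 with an estimated correlation). The GABA list was missed without wild-type CLIP 3 (camera adjusted p in limma = 0.0575) or knockout CLIP 1 (0.0741) or 3 (0.0586). The astrocyte list was missed without wild-type CLIP 2 (camera adjusted p in limma = 0.0574) or 4 (0.183) or knockout CLIP 3 (0.087) or 4 (0.333). It was also missed with the replicate number as a block (camera adjusted p in limma = 0.0548). With single arrays left out, medians ran from −0.134 to −0.073 for stress response, −0.165 to −0.086 for GABA receptors and −0.125 to −0.046 for astrocyte markers. No gene of these 3 lists passed, over all genes or adjusted over the list alone.

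The remaining lists did not pass in the CLIP comparison. Camera in limma gave adjusted p = 0.268 for the group 1 metabotropic glutamate pathway (31 genes; 2 higher adjusted over the list alone), 0.285 for ionotropic glutamate receptors (29), 0.85 for presynaptic release (48; Ppfia3 higher over all genes, 3 adjusted over the list alone) and 0.726 for the FMRP family and RNA granules (35). It gave 0.189 for cytoplasmic ribosomal proteins (78), 0.209 for oxidative phosphorylation (75), 0.189 for core histones (56) and 0.934 for immediate early genes (28). Among cell-type markers, excitatory neurons (20; 1 higher adjusted over the list alone) gave 0.885, inhibitory neurons (19) 0.704, oligodendrocyte lineage (18) 0.321 and microglia (22) 0.652. Endothelial and meningeal cells (22) gave 0.189, cycling progenitors (25) 0.462, blood (11) 0.809 and sex-linked transcripts (8) 0.885. Some of these passed when 1 array was left out, and oxidative phosphorylation also with the replicate number as a block (camera adjusted p in limma = 0.0274). Oxidative phosphorylation was higher without wild-type CLIP 1 (camera adjusted p in limma = 2.57e-06) or knockout CLIP 2 (0.00309) or 3 (8.21e-04). Ribosomal proteins were lower without wild-type CLIP 2 (0.0242) or 4 (0.00337) or knockout CLIP 1 (5.46e-05) or 5 (2.34e-04), and histones without wild-type CLIP 5 (0.00941) or knockout CLIP 1 (2.89e-04) or 5 (1.81e-05). Ionotropic receptors passed without wild-type CLIP 1 (0.0401), endothelial markers without wild-type CLIP 3 (0.0412) or knockout CLIP 1 (0.0423) or 5 (0.0377), and cycling progenitors without knockout CLIP 3 (0.0387). All 6 had camera adjusted p = 0.897 in limma with an estimated correlation on all arrays.

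**Figure D3:**
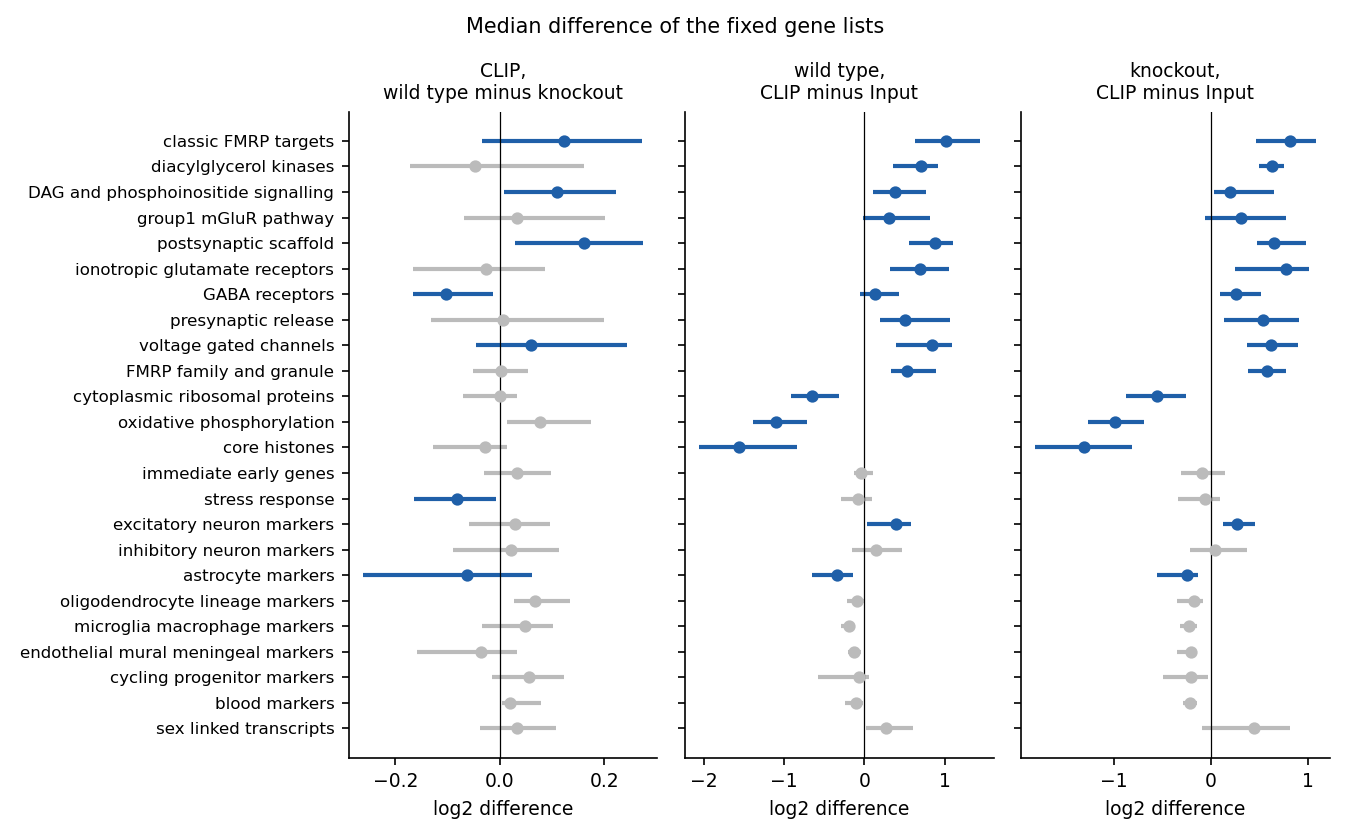
Median log2 difference, with quartiles, of the 24 gene lists between genotypes in CLIP and between CLIP and Input in either genotype. Blue marks lists past adjusted p 0.05 in limma's camera.

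The genotype by fraction interaction sets the enrichment of an RNA in wild-type CLIP over Input against its enrichment in the knockout, and so takes off differences in RNA level where the levels lie above the floor. Dgkk led it, enriched by 2.46 log2 more in wild type (SE 0.25, limma adjusted p = 3.87e-05). The others that passed were 2610507B11Rik (1.28, SE 0.18, limma adjusted p = 0.00369), Unc13c (1.5, SE 0.23, limma adjusted p = 0.012), Fmr1 (1.02, SE 0.17, limma adjusted p = 0.0323) and Ppfia3 (0.93, SE 0.16, limma adjusted p = 0.0485). All 5 were higher and 0 lower, and at unadjusted p under 0.05 there were 672 higher and 423 lower, fewer than the 1228 of chance. With the culture as a block, 2 remained, Dgkk and 2610507B11Rik; limma adjusted p was then 0.106 for Unc13c, 0.106 for Fmr1 and 0.133 for Ppfia3. After quantile normalization 7 were higher and 2 lower, the 2 being Mnd1 (−0.93 and limma adjusted p = 0.0731 as deposited) and Ewsr1 (−0.82 and limma adjusted p = 0.201 as deposited). The count was 8 without wild-type CLIP 2 and 3 without wild-type CLIP 1 or 5, knockout CLIP 1, 3 or 5, wild-type Input 1, 2 or 3, or knockout Input 3 or 5. Dgkk, 2610507B11Rik and Unc13c passed in all 20 refits.

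Fmr1 and Ppfia3 stand on weaker ground in the interaction, and Unc13c too was missed with the culture as a block. Fmr1 was missed in 14 of 20 refits (limma adjusted p up to 0.102), and passed only without wild-type CLIP 2 or 3, knockout CLIP 4, wild-type Input 5 or knockout Input 1 or 2. Ppfia3 was missed in 16 (up to 0.145), and passed only without wild-type CLIP 2, knockout CLIP 2, wild-type Input 4 or knockout Input 4. For Fmr1 in knockout, and for Dgkk and Unc13c outside wild-type CLIP, levels lie near the bottom of the scale, where log2 differences are compressed. Their enrichment in knockout is then a difference of floor values with no known size or sign, so that these interaction values are neither exact nor lower bounds. Mnd1, lower in the interaction, passed without wild-type CLIP 4 (limma adjusted p = 0.0314) or knockout CLIP 2 (0.012). Its levels outside wild-type Input (3.98 to 4.17) lie near the floor as well, so the same limit holds for its interaction value.

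Classic FMRP targets were enriched more in wild type than in knockout as a set. The knockout itself sets the difference of Fmr1, a member of the list. Not taken relative to all genes, the median interaction was 0.183 without Fmr1, against 0.188 for the full list of targets. Their median interaction was 0.16 above that of all genes (96 genes; Fmr1 past over all genes; 5 higher adjusted over the list alone; camera adjusted p = 3.98e-08 in limma, and adjusted p = 0.832 with an estimated correlation), and the list passed in all 20 refits, with medians from 0.07 to 0.22. Diacylglycerol and phosphoinositide signalling (0.10 above all genes; 2 higher adjusted over the list alone) gave camera adjusted p = 0.00825 in limma, and adjusted p = 0.644 with an estimated correlation. Postsynaptic scaffold (0.13 above all genes; 0 adjusted over the list alone) gave 0.00825 too, and voltage-gated channels (0.05; 1 higher adjusted over the list alone) 0.0335, each with adjusted p = 0.832 with an estimated correlation. Ribosomal proteins (−0.11 against all genes; adjusted p = 5.06e-05 in limma's camera), core histones (−0.21; 1.53e-04) and oxidative phosphorylation (−0.08; 0.0149) were lower, without a gene past, and all 3 had adjusted p = 0.832 with an estimated correlation.

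Single arrays decided several of these interaction sets. Lipid signalling was missed without wild-type CLIP 1 (camera adjusted p in limma = 0.127), knockout CLIP 4 (0.0645) or knockout Input 1 (0.0745), and postsynaptic scaffold without wild-type CLIP 1 (0.148), wild-type Input 2 (0.0682) or knockout Input 1 (0.124) or 3 (0.153). Voltage-gated channels were missed without wild-type CLIP 1 or 5, knockout CLIP 2 or 4, wild-type Input 2 or 3 or knockout Input 1 or 3 (0.0704 to 0.422). Ribosomal proteins were missed without knockout CLIP 2 (0.133), and histones without wild-type CLIP 1 (0.0724) or knockout CLIP 3 (0.09). Oxidative phosphorylation was missed without wild-type CLIP 1, knockout CLIP 2, 3 or 4, wild-type Input 1 or knockout Input 2, 4 or 5. Medians moved too: 0.057 to 0.118 for lipid signalling, 0.027 to 0.174 for postsynaptic scaffold, 0.0065 to 0.180 for voltage-gated channels, −0.165 to −0.039 for ribosomal proteins, −0.317 to −0.084 for histones and −0.174 to 0.042 for oxidative phosphorylation. The number of lists fell from 7 to 2 without wild-type CLIP 1 and to 4 without knockout CLIP 2.

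Other lists did not pass in the interaction as fitted. GABA receptors (−0.13 against all genes; camera adjusted p = 0.0813 in limma) passed as lower with the culture as a block (0.0279), and without wild-type CLIP 5 (0.0413), knockout CLIP 4 (0.0466) or 5 (0.0383), wild-type Input 3 (0.0288) or knockout Input 1 (0.00388) or 3 (0.0127). Presynaptic release (0.324; Ppfia3 higher over all genes, 2 adjusted over the list alone) passed without knockout Input 2 (0.0159). With an estimated correlation, on all arrays, both lists had camera adjusted p = 0.832 in limma. Camera in limma gave adjusted p = 0.355 for diacylglycerol kinases (Dgkk alone higher, also adjusted over the list alone), 0.496 for the group 1 metabotropic glutamate pathway, 0.795 for ionotropic glutamate receptors and 0.542 for the FMRP family. It gave 0.324 for immediate early genes, 0.276 for stress response, 0.909 for excitatory and 0.542 for inhibitory neuron markers, 0.276 for astrocytes and 0.315 for oligodendrocyte lineage. Microglia gave 0.909, endothelial cells 0.315, cycling progenitors 0.464, blood 0.355 and sex-linked transcripts 0.909. No gene of these lists other than Dgkk and Ppfia3 passed over all genes.

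In the total RNA of the neurons, Fmr1 alone passed between the genotypes. Fmr1 was lower in knockout by 1.55 log2 (−1.55, SE 0.13, at least 2.94-fold, limma adjusted p = 6.35e-04) and was the only one of 24551 features to pass, in every refit. At unadjusted p under 0.05 there were 398 higher and 550 lower, fewer than the 1228 expected by chance. Completely parted groups numbered 67 higher and 104 lower, against about 195 by chance. Among the features of lowest p that did not pass were Mnd1 (−0.74, limma adjusted p = 0.0645), R74862 (−0.93, limma adjusted p = 0.411), Neurl2 (−0.83, limma adjusted p = 0.706) and the histone methyltransferase gene Mll2 (now Kmt2d, 0.72, limma adjusted p = 1). The diacylglycerol kinases gave no call in Input (Dgkk 0.06, Dgkg 0.19, Dgkz −0.17, Dgkb −0.14; camera adjusted p = 0.868 in limma). The comparison is blunt: of features given an artificial difference of 1 log2, 74% were recovered, and of those given 0.5, 14%.

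Gene sets of energy supply and protein synthesis lay lower in knockout Input, though no single gene passed. Of 75 oxidative phosphorylation genes, only 15 were above 0, and their median lay below that of all genes (−0.18, camera adjusted p = 5.9e-16 in limma, and adjusted p = 0.722 with an estimated correlation). Examples are the respiratory chain genes Uqcrb (−0.58) and Ndufc1 (−0.48), both at limma adjusted p = 1. Ribosomal proteins (78 genes; −0.08 against all genes; camera adjusted p = 1.89e-05 in limma) and core histones (56; −0.11; 3.03e-04) were lower as well, each with adjusted p = 0.957 with an estimated correlation. Markers of endothelial and meningeal cells moved the other way (22 genes; 0.11 above all genes; Acta2, 0.76; Vtn, 0.47; camera adjusted p = 0.00122 in limma, and adjusted p = 0.957 with an estimated correlation). Oxidative phosphorylation (medians −0.214 to −0.160) and ribosomal proteins (−0.119 to −0.054) passed in all 10 refits. Histones were missed without wild-type Input 2 (camera adjusted p in limma = 0.0635) or 5 (0.056) or knockout Input 1 (0.153) or 5 (0.116), and endothelial markers without knockout Input 4 (0.0597). Medians ran from −0.243 (without wild-type Input 1) to −0.041 for histones and from 0.060 to 0.161 for endothelial markers. No gene of these 4 lists passed, over all genes or adjusted over the list alone.

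Classic FMRP targets did not pass as a set in Input (1 lower, Fmr1, over all genes and adjusted over the list alone; camera adjusted p = 0.0933 in limma). They passed as higher in knockout without wild-type Input 1 (camera adjusted p in limma = 0.0179) or 4 (0.0121) or knockout Input 2 (7.77e-07) or 4 (3.63e-04). Ionotropic glutamate receptors (0.188) passed without wild-type Input 1 (0.0379) or 4 (0.0248) or knockout Input 2 (0.0077) or 4 (0.00404), and stress response (0.258) without wild-type Input 1 (0.00711) or knockout Input 2 (0.00565) or 4 (0.0189). Presynaptic release (0.538) and voltage-gated channels (0.813) passed only without knockout Input 2 (0.0104 and 0.024), and postsynaptic scaffold (0.388) only without knockout Input 3 (0.0457). All 6 had camera adjusted p = 0.957 in limma with an estimated correlation on all arrays. The number of lists was 4, and 7 without wild-type Input 1 and 9 without knockout Input 2. Camera in limma gave adjusted p = 0.868 for lipid signalling, the group 1 metabotropic glutamate pathway, the FMRP family, microglia, cycling progenitors and sex-linked transcripts. It gave 0.893 for GABA receptors and excitatory neurons, 0.333 for immediate early genes, 0.337 for inhibitory neurons, 0.488 for astrocytes, 0.813 for oligodendrocyte lineage and 0.538 for blood.

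CLIP and Input differ in a large share of RNAs, with and without FMRP. In wild type, limma called 4174 features higher and 4396 lower in CLIP (8570 of 24551), and in knockout 3980 higher and 4834 lower (8814). Differences beyond 1 log2 numbered 1282 higher and 836 lower in wild type, and 1037 higher and 663 lower in knockout. Across features the enrichment in wild type followed that in knockout closely (r = 0.913, Spearman's rho 0.851; features of an array are not independent replicates). Of the 4174 features higher in wild type, 3269 (78.3%) were also higher in knockout, where independent lists would share 677, and 2 were lower there. Of the 4396 lower, 3010 (68.5%) were shared, where independent lists would share 866, and 0 were higher in knockout. The genotype difference in CLIP followed that in Input little (r = 0.0889, rho 0.0677 across features). These are 2 of the relations across features that were computed; those over splits of the arrays, with gene span and with RNA abundance have tests of their own. The median feature lay 0.09 lower in CLIP in wild type (−0.09) and 0.13 lower in knockout (−0.13), and −0.01 and −0.02 after quantile normalization; list medians here are therefore relative to all genes.

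**Figure D4:**
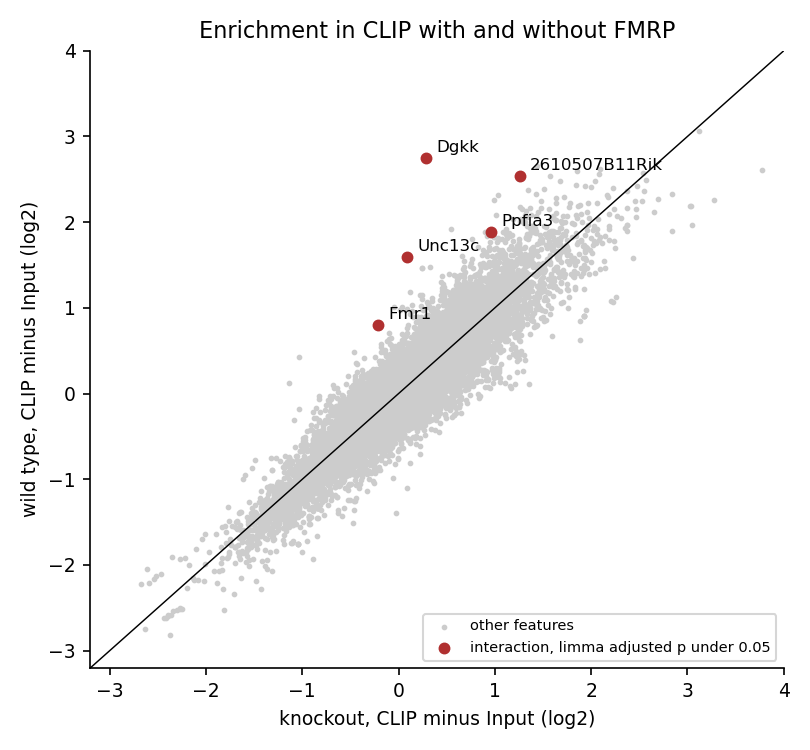
CLIP minus Input in wild type against the same difference in knockout, for every feature, with the line of equality. Red marks the 5 features past limma adjusted p 0.05 in the interaction.

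In wild type, the noncoding RNA Meg3 and Dgkk mRNA topped the CLIP side. Meg3, which is imprinted, was higher by 3.07 (SE 0.28, limma adjusted p = 3.95e-08), Dgkk by 2.75 (SE 0.17, limma adjusted p = 5.12e-10), and Gm608 by 2.65. The chromatin remodellers Chd7 (2.62) and Chd3 (2.57), the nucleosome remodelling factor Bptf (2.57), the myosin gene Myo9a (2.60) and Cspp1 (2.61) followed. For Chd7, 25 of 30 features were higher, and for Cspp1 12 of 14 were higher and 1 lower. In knockout, Cspp1 (3.78, SE 0.36, limma adjusted p = 1.72e-07) and Meg3 (3.12, limma adjusted p = 8.37e-08) led. The small nucleolar RNA host genes Snhg1 (3.05) and Gas5 (2.84) and the splicing factor Rbm25 (3.03 in each of 2 features) followed. Input levels lie near the floor for Snhg1 (3.94) and Cspp1 (4.40) in knockout and for Dgkk (4.34) and Chd7 (4.43) in wild type. Their differences are therefore lower bounds and their ranks are not exact. The lowest in wild-type CLIP were histone mRNAs, which lack a poly(A) tail: Hist1h4c (−2.82, limma adjusted p = 1.29e-07), Hist1h4f (−2.74), Hist2h3b (−2.62) and Hist1h3b (−2.61). In knockout they were Hist1h4f (−2.63), Hist2h3b (−2.44), Hist1h3b (−2.42) and Hist2h3c1 (−2.40). Histone genes of a family share most of their sequence, so these features are not independent.

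Enrichment of Dgkk and Fmr1 could hardly be read in knockout, where the Fmr1 mRNA is lost and Dgkk lies little above the floor. There, neither Dgkk (0.29, limma adjusted p = 0.193) nor Fmr1 (−0.22, limma adjusted p = 0.158) passed between CLIP and Input, while in wild type Fmr1 was higher by 0.80 (limma adjusted p = 1.8e-05). The other diacylglycerol kinases were mostly richer in CLIP in either genotype: Dgkh (1.32 in wild type, 1.03 in knockout), Dgkd (0.97, 0.72), Dgkz in 1 of 3 features (1.13, 0.80), Dgke (0.75, 0.76), Dgkb (0.66, 0.85), Dgki (0.47, 0.60) and Dgkg (0.76, 0.61). Dgkq and Dgka passed in knockout (0.64 and 0.47) but not in wild type (0.21, limma adjusted p = 0.312, and 0.17, limma adjusted p = 0.408). In knockout, Dgka was missed without knockout CLIP 1 (limma adjusted p = 0.0572) or 5 (0.0565) or knockout Input 3 (0.0582) or 4 (0.0585). Dgkg was missed there without knockout CLIP 1 (limma adjusted p = 0.0995) or 5 (0.0733) or knockout Input 2 (0.0665), 3 (0.0568) or 4 (0.0955). Counted by gene, 8 of 10 were higher and 0 lower in wild type (8 adjusted over the list alone; camera adjusted p = 1.31e-05 in limma, and adjusted p = 0.0147 with an estimated correlation). In knockout 8 were higher and 0 lower (9 adjusted over the list alone; 1.97e-05, and adjusted p = 0.0183 with an estimated correlation).

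Synaptic and FMRP-bound mRNAs were richer in CLIP in both genotypes. Of 96 classic targets, 82 were higher and 3 lower in wild type (85 and 4 adjusted over the list alone), among them Agap2 (2.03), Kif1a (1.64) and Mtor (1.62). Their median was 1.11 above that of all genes (camera adjusted p = 8.62e-37 in limma, and adjusted p = 0.0147 with an estimated correlation). In knockout 78 were higher and 2 lower (84 and 3 adjusted over the list alone; 0.94 above all genes; camera adjusted p = 3.6e-32 in limma, and adjusted p = 0.0183 with an estimated correlation). The postsynaptic scaffold list had 35 higher and 0 lower in wild type (36 and 0 adjusted over the list alone; Shank1, 2.18; Kalrn, 1.93; camera adjusted p = 2.27e-21 in limma, and adjusted p = 0.0033 with an estimated correlation). In knockout it had 35 and 1 (36 and 1 adjusted over the list alone; 7.08e-20, and adjusted p = 0.0092 with an estimated correlation). Voltage-gated channels had 40 higher in wild type and 38 in knockout, 0 lower (43 and 40 adjusted over the list alone; Cacna1d, 1.55; camera adjusted p = 7.81e-19 and 3.27e-17 in limma, and adjusted p = 0.0107 and 0.0153 with an estimated correlation). Enrichment of known FMRP ligands over Input thus occurred in neurons without FMRP.

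Further neuronal lists were richer in CLIP too. Presynaptic release had 31 higher and 2 lower in wild type and 27 and 2 in knockout (31 and 3, and 30 and 3, adjusted over the list alone; Ppfia3, 1.89; camera adjusted p = 7.87e-12 and 4.98e-12 in limma, and adjusted p = 0.0197 and 0.0183 with an estimated correlation). Ionotropic glutamate receptors had 18 and 1, and 19 and 0 (19 and 1, and 19 and 0, adjusted over the list alone; Grik5, 1.88; camera adjusted p = 1.05e-08 and 3.75e-09 in limma, and adjusted p = 0.0197 and 0.0183 with an estimated correlation). Diacylglycerol and phosphoinositide signalling had 34 and 2, and 26 and 2 (36 and 2, and 26 and 2, adjusted over the list alone; Itpr1, 1.47; camera adjusted p = 5.33e-10 and 2.3e-07 in limma, and adjusted p = 0.0033 and 0.0106 with an estimated correlation). The group 1 metabotropic glutamate pathway had 15 and 5, and 12 and 2 (16 and 6, and 13 and 3, adjusted over the list alone; camera adjusted p = 2.18e-04 and 1.72e-04 in limma, and adjusted p = 0.147 and 0.139 with an estimated correlation). The FMRP family and granule list had 23 and 1, and 24 and 0 (24 and 1, and 27 and 1, adjusted over the list alone; Dicer1, 1.66; camera adjusted p = 3.45e-09 and 3.41e-11 in limma, and adjusted p = 0.0995 and 0.0693 with an estimated correlation). Excitatory neuron markers had 9 and 7 higher, 0 lower (the same adjusted over the list alone; Camk2a, 0.80; camera adjusted p = 0.00213 and 0.00114 in limma, and adjusted p = 0.172 and 0.16 with an estimated correlation). GABA receptors had 4 and 1, and 5 and 0 (4 and 1, and 7 and 0, adjusted over the list alone; camera adjusted p = 0.0392 and 0.00114 in limma, and adjusted p = 0.535 and 0.259 with an estimated correlation). In wild type the GABA list was missed without wild-type CLIP 4 (camera adjusted p in limma = 0.0603) or 5 (0.0652) or wild-type Input 2 (0.0693) or 3 (0.0833).

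Lists of housekeeping mRNAs were poorer in CLIP in both genotypes. Oxidative phosphorylation had 72 of 75 genes lower in wild type and 71 in knockout, 0 higher (72 and 72 lower adjusted over the list alone; Ndufa7, −1.74; Atp5g1, −1.58), with medians −1.01 and −0.86 against all genes. Its camera adjusted p was 9.78e-31 and 8.15e-28 in limma, and adjusted p = 0.0995 and 0.123 with an estimated correlation. Core histones had 51 and 50 of 56 lower, 0 higher (53 and 51 adjusted over the list alone; camera adjusted p = 9.67e-27 and 6.48e-23 in limma, and adjusted p = 0.0942 and 0.119 with an estimated correlation). Ribosomal proteins had 61 and 57 of 78 lower and 1 higher in either genotype (65 lower and 1 higher, and 60 lower and 2 higher, adjusted over the list alone; Rps13, −1.37; Rpl9, −1.37; camera adjusted p = 7.72e-22 and 4.07e-16 in limma, and adjusted p = 0.158 and 0.242 with an estimated correlation). Astrocyte markers were lower alongside (9 and 7 lower, 1 higher; 9 and 8 lower and 1 higher adjusted over the list alone; Aldoc, −1.55; Slc1a3, −0.95; camera adjusted p = 0.00466 and 0.018 in limma, and adjusted p = 0.185 and 0.271 with an estimated correlation). In knockout the astrocyte list was missed without knockout Input 3 (camera adjusted p in limma = 0.0598).

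Lists that did not pass between CLIP and Input still held changed genes. Immediate early genes had 5 higher and 2 lower in wild type and 3 and 5 in knockout (5 and 2, and 3 and 2, adjusted over the list alone; camera adjusted p = 0.561 and 0.902 in limma). Stress response genes had 3 and 4, and 4 and 6 (3 and 3, and 4 and 5, adjusted over the list alone; 0.513 and 0.902). Inhibitory neuron markers had 6 and 3, and 5 and 2 (7 and 4, and 5 and 4, adjusted over the list alone; 0.229 and 0.31), and cycling progenitors 4 and 7, and 3 and 7 (4 and 7, and 3 and 8, adjusted over the list alone; 0.556 and 0.285). Of oligodendrocyte lineage markers 3 and 5 were lower, also adjusted over the list alone (0.369 and 0.104), and of microglia markers 4 and 5 (4 and 4 adjusted over the list alone; 0.0833 and 0.0544), 0 higher. Endothelial markers had 1 and 2, and 1 and 4 (1 and 0, and 1 and 4, adjusted over the list alone; 0.434 and 0.121). Blood markers had 1 lower in either genotype (0 and 1 adjusted over the list alone; 0.513 and 0.199), and sex-linked transcripts 0 (0.434 and 0.459). In wild type, microglia passed without wild-type CLIP 3 (camera adjusted p in limma = 0.0446) or wild-type Input 1 (0.0368). In knockout they passed without wild-type CLIP 3 (0.0481), knockout CLIP 4 (0.0447), wild-type Input 3 (0.0487) or knockout Input 1 (0.0234) or 3 (0.0238), and endothelial markers without knockout CLIP 4 (0.0426). With the culture as a block both lists passed in knockout (0.0343 for microglia and 0.0464 for endothelial markers). With an estimated correlation, on all arrays, camera adjusted p in limma was 0.552 for microglia and 0.569 for endothelial markers in knockout, and 0.568 for microglia in wild type. Oligodendrocyte lineage markers passed as lower in knockout in 2 of 25 alternatives (lowest camera adjusted p in limma 0.0251), and gave 0.32 with an estimated correlation.

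The authors' deposited table ranks RNAs by the ratio of CLIP to Input in wild type over that in knockout. On these same arrays, Dgkk has the largest fold of the genes named here, 5.80. Unc13c stands at 2.97, 2610507B11Rik at 2.42, Fmr1 at 2.06, Ppfia3 at 1.9, Tln2 at 1.77 and Ogdh at 1.65. For Dgkk, Unc13c and Fmr1 these folds rest on levels near the floor and are neither exact nor lower bounds. The p-value column of the authors' deposited table is under 0.05 for 1370 features, 912 higher and 458 lower in wild type, against 1228 expected by chance. After Benjamini-Hochberg adjustment of that column, 0 stay under 0.05, the lowest value being 0.0916. Its permutation p column is under 0.05 for 1202 features, and for 1065 in the comparison of Input arrays. Both counts lie below the 1228 expected by chance. After Benjamini-Hochberg adjustment of these permutation p-values 0 stay under 0.05, the lowest being 0.322 and 0.515.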

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

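The tests of RNA level in the cultures, of FMRP binding for the enrichment shared by both genotypes, of the spread between cultures and of Input hybridisation alone were chosen only after the result was seen; the other tests of this part were set beforehand, but their ranges with single arrays left out were added later. The RNA level test was first made on the 25 features called in CLIP, with the same outcome, and then widened.

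A test of the difference between genotypes in CLIP enrichment singled out 5 genes and 7 gene lists. The genes are Dgkk (2.46), 2610507B11Rik (1.28), Unc13c (1.5), Fmr1 (1.02) and Ppfia3 (0.93). This fit, also used for the groupings below, does not pair the CLIP and Input arrays of a culture. With the culture as a block, only Dgkk and 2610507B11Rik passed in limma. The lists, as medians relative to all genes, are classic FMRP targets (0.158), diacylglycerol and phosphoinositide signalling (0.102), postsynaptic scaffold (0.132) and voltage-gated channels (0.0468), and, lower, ribosomal proteins (−0.109), oxidative phosphorylation (−0.0785) and core histones (−0.215). With an estimated correlation none of the 7 lists passed (limma camera adjusted p = 0.644 to 0.832). Of 100 groupings of the 10 cultures tried, the real one included, only 1 gave as many interaction genes as the real one, and another grouping gave at most 1 gene.

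Single arrays far from the other 4 of their group were found in 19 of 216 groups of values over 54 features, where chance alone gives about 10.8. Wild-type Input 1 holds 8 of them: the histone genes Hist1h4f (7.70; next 8.59), Hist2h3b (9.58; next 10.65), Hist1h3b (9.48), Hist1h3d (9.48), Hist1h3c (9.43), Hist2h3c1 (9.18) and Hist1h3e (9.43), all low, and Ptges3 (8.22; next 7.29). Knockout Input 1 holds 3, all high: Dgkd (7.39; next 7.04), Mll2 (6.44; next 5.74) and Chd7 (5.81; next 4.71). Wild-type CLIP 1 was high for Dgkb (7.32; next 6.74) and Mll2 (7.04; next 5.85), and knockout CLIP 1 for Dgkq (6.42; next 5.73). Knockout CLIP 2 was low for Tmem167b (7.21; next 7.35) and high for Ewsr1 (6.25; next 6.01), and knockout CLIP 4 low for Gpm6a (9.74; next 10.11). Wild-type Input 2 was low for Tmem167b (6.60; next 7.33) and wild-type Input 4 high for Snhg1 (6.25; next 4.04). Histone genes of a family share sequence, so the 7 in wild-type Input 1 count as few independent observations.

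Other groupings of the same arrays show how far the counts rest on the labels. For CLIP, 3 of 100 groupings gave at least 27 features, the real one among them; the others gave 272 and 35. The grouping with 272 sets wild-type CLIP 1 with knockout CLIP 1, 2, 3 and 5 against the rest, in effect an exchange of wild-type CLIP 1 and knockout CLIP 4, although Fmr1 parts the genotypes in every array. For Input, 5 of 100 groupings gave at least the 1 feature of the real one, and 1 of them gave 741, with knockout Input 1 and 3 and wild-type Input 1, 4 and 5 on 1 side. The arrays thus hold structure other than genotype, whose source the labels do not give. In CLIP it overlaps with genotype, since only wild-type CLIP 1 and knockout CLIP 4 change sides in the grouping with 272. The third principal component parts the CLIP arrays alike (wild-type 2 to 5 and knockout 4 from 8.43 to 16.91, the others from −21.97 to 0.11). How much of the 27 calls and the list shifts in CLIP comes from it was not tested. For CLIP against Input, only 1 of 100 groupings reached the real count in wild type (8570; the next 3377) and only 1 in knockout (8814; the next 7340). Among groupings that part all 5 pairs, the highest others were 11 and 1.

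More features were higher than lower in wild-type CLIP. The RNA level of the cultures is argued against as the main cause. Over all features higher at unadjusted p under 0.05, the median Input difference is 0.0344 of the CLIP difference (−0.028 to 0.135 with single Input arrays left out). Picking features by their CLIP difference lowers this fraction, as do features higher by chance, so a part due to RNA level stays open. Genomic span is argued against as the whole cause for classic targets other than Fmr1. Their median stands at percentile 100 of 10000 random lists matched on span (99.78 at lowest with single arrays left out). The length of the mRNAs was not measured and stays open. FMRP binding, the difference between the genotypes, fits for these targets (percentile 99.99 among lists matched on mean level and knockout enrichment). But that matching uses the knockout CLIP arrays that also enter the difference tested, which can favour the targets. Random lists also ignore correlation between genes. The full list, Fmr1 included, gives limma camera adjusted p = 0.36 with an estimated correlation and adjusted exact permutation p = 0.381 over cultures. Scaling and a stronger general recovery cannot be told apart from FMRP binding for the excess at large. After scaling, the ratio of higher to lower features was at lowest 1.33 (from 1.97). With single arrays left out this ratio ran from 0.80 (without knockout CLIP 4) to 2.13. The correlation with knockout enrichment ran from −0.246 to 0.411 over 20 splits.

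RNAs richer in CLIP than in Input were largely the same in both genotypes. Neurons without FMRP cannot owe their enrichment to it, and 78.3% of the features higher in wild type were also higher there. This share restates the pattern, and its bounds were set after it was seen. It is therefore no separate test of FMRP binding as the main source in wild type. Gene length fits as genomic span, while the length of the mRNAs was not measured. Knockout enrichment rose with span (Spearman's rho 0.447 across genes, which are not independent replicates). It went from a median of −0.28 in the shortest 2066 genes to 0.26 in the longest 2066. Of all genes, 97.1% have a span. RNA abundance cannot be told apart from other sources (rho 0.238 with the wild-type Input level, a set of arrays outside the difference), because the value lies between those set beforehand for either outcome. Binding of the antibody to other proteins was not tested.

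Oxidative phosphorylation mRNAs were lower in knockout Input. The spread between cultures cannot be told apart from genotype, since the list mean gives exact permutation p = 0.0159 but 0.382 after adjustment over the lists. A shift of Input arrays towards the makeup of CLIP cannot be told apart either (median r 0.0543 across genes over 200 splits, from −0.240 to 0.428, so that the sign depends on the split). The same holds for hybridisation of Input arrays alone, since the list's CLIP difference is 0.328 of its Input difference but runs from −0.208 to 1.05 of it with single arrays left out. No explanation was excluded, and loss of FMRP, the difference the design names, stays open as well.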

How the results depend on the processing

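The filter on features above 4 in at least 2 arrays was the only alternative chosen after seeing the data; it gave 21, 1, 7799, 7834 and 4 features for CLIP between genotypes, Input, CLIP against Input in wild type and knockout, and the interaction. The alternative log2(value + 16) was not run, as the values are already log2. For moved counts the cause was not tested except where stated.

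Between genotypes Fmr1 kept its direction and call wherever it was tested (CLIP 2.50 to 2.65, Input −1.60 to −1.47 with arrays left out). The CLIP count of 27 became 14 after quantile normalization, 8 after median centring, 13 with a trended robust prior, 67 with array weights, 71 at adjusted p under 0.1, and 4 to 61 with single arrays left out. With the replicate number as a block it was 3; the numbers pair cultures of different genotypes only by label, same-numbered arrays correlating at 0.442 to −0.139 in CLIP and 0.547 to −0.266 in Input. The Input count of 1 became 0 without the lower 50% of features, as Fmr1 itself was left out, 2 with array weights, 3 in a fit of all 20 arrays and 2 at adjusted p under 0.1.

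The counts of CLIP against Input kept within 1.5 times under every alternative in wild type, and in knockout fell from 8814 to 5609 only with a log2 difference of at least 0.5, a stricter threshold by construction. With the culture as a block they were 9120 and 9503. In wild type the 2 low Dgkz features turned to 0.317 with 1 value per symbol, as they are then averaged with the other one.

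The interaction count of 5 became 9 after quantile normalization, 3 after median centring, 8 after quantile normalization within fractions, 3 and 1 without the lowest tercile and the lower 50% of features, 2 with the culture as a block, and 3 to 8 with single arrays left out. Dgkk passed under each of them that kept it; its mean lies in the lower 50%, so that filter left it out.

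With an estimated inter-gene correlation, 0 lists remained in CLIP, 0 in Input, 7 in wild-type and 7 in knockout CLIP against Input, and 0 in the interaction, from 7, 4, 15, 15 and 7. With arrays left out, Input gave 3 to 9 lists and the interaction 2 to 8; after quantile normalization the interaction gave 3. Ribosomal proteins in the interaction then turned to 0.0026 and oxidative phosphorylation to 0.0385; the latter ran from −0.174 to 0.0423 with arrays left out. The median of all genes for CLIP against Input moved from −0.13 to −0.02 in knockout. Some lists were missed in more alternatives than told above. Of 15, astrocyte markers were missed in 7 in CLIP, and ribosomal proteins in 2 and histones in 6 in Input. Of 25, voltage-gated channels were missed in 11 and histones in 4 in the interaction. In wild-type CLIP against Input, GABA receptors were missed in 7 of 25 and excitatory neuron markers in 2. Signal over background limits what low features can show: differences near the bottom of the scale are compressed, and filters remove them.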

Other observations

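The tests of functional terms over all annotated genes and of expressed genes beside Fmr1 were chosen only after the result was seen; those of the 20 nearest genes and of amino acid response genes were set before.

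Functional annotation adds groups that the fixed lists do not hold (614 terms of 15 to 300 genes, tested in each comparison with limma's camera; examples from the genotype comparisons are given). In wild-type CLIP, regulators of small GTPases lay higher (33 genes, median 0.13 above all genes, limma camera adjusted p = 1.22e-04), with myosin complex (45, 0.07, 0.00497), proteins that shape the actin skeleton of neurites and spines. Lower in wild-type CLIP were amino acid transmembrane transport (35, −0.14, 2.45e-04), mRNA processing (244, −0.07, 0.00497), RNA splicing (185, −0.07, 0.00497), sodium ion export (53, −0.07, 0.00929), neurotransmitter secretion (18, −0.10, 0.0344) and phospholipid biosynthesis (46, −0.09, 0.0438). Every one of these had adjusted p = 1 with an estimated correlation, and no gene of the 2 higher terms passed limma singly.

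Knockout Input had lower levels of the respiratory chain (54 genes, −0.22 against all genes, limma camera adjusted p = 1.5e-17), the ribosome (138, −0.12, 4.26e-13), the large subunit of the mitochondrial ribosome (17, −0.20, 6.03e-05) and the proteasome (57, −0.10, 0.00726). Amino acid transmembrane transport (35, 0.12, 0.00153) and axon guidance (72, 0.07, 0.034) were higher. With an estimated correlation all had adjusted p = 0.984, so these shifts do not stand out from the joint variation of the genes between cultures.

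Classic FMRP targets other than Fmr1 (95 genes) had a median CLIP difference of 0.120, where 95% of random lists matched on mean level and knockout enrichment stayed below 0.049, and a median interaction of 0.183. Matched on genomic span as well, they stood at percentile 99.82. Both matchings use the knockout CLIP arrays that also enter the differences tested, which can favour the targets. Treating the 5 cultures per genotype as the unit, the mean of the full list, Fmr1 included, differed in CLIP at exact permutation p = 0.0397. After adjustment over the 24 lists this exact permutation p was 0.381.

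The knockout carries DNA around Fmr1 that may come from another mouse strain, which could shift the genes beside it. The 20 nearest measured genes cannot settle this (percentile 50.62 of random lists). In wild-type Input, 11 of them lie at or under the level of Fmr1 in knockout Input, where a fall could not show. For the 20 nearest genes with a level of 5 or more in wild-type Input, the median absolute difference, 0.164, stands at percentile 93.37 of random lists of such genes, and from 37.87 to 95.97 with single Input arrays left out. The lowest limma adjusted p over these 20 is 0.763. Such a shift therefore cannot be told apart from the spread between arrays.

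Amino acid transport genes were lower in wild-type CLIP and higher in knockout Input (0.158 over both fractions, exact permutation p = 0.0159 over cultures and 0.0477 adjusted over 3 sets, which is no separate test, as the term was picked from 614 on these arrays), and the stress list was lower in wild-type CLIP but did not pass in Input (limma camera adjusted p = 0.258). An amino acid response of the knockout cultures might underlie this. Over 32 response genes outside the lists, chosen from general knowledge, the knockout mean was higher by 0.117 (exact permutation p = 0.294, 5 against 5 cultures). Of the 32 genes, 22 were higher in both fractions. Camera in limma gave them unadjusted p = 0.00154 in CLIP and 7.34e-04 in Input. This permutation p met the bound set beforehand for counting against the explanation, but with 5 cultures per genotype a missed p excludes nothing. The explanation thus cannot be told apart from chance. The stress list differed by 0.0957 over both fractions (exact permutation p = 0.135).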
